A study of Mus musculus with 6 samples.

How the data were processed

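The data are ATAC-seq peaks of Treg cells from mice with intact Bcl11b and from mice labelled Bcl11b knockout, with 3 samples per group. Per the submitters' processing notes, the tools included FastQC, Trim Galore 0.4.2, cutadapt 1.12, HISAT2 2.1.0, SAMtools 1.3, HOMER 4.10.1 and deepTools, with genome build mm10. The notes do not say which tool did what, and the peak threshold, the shift of reads for transposase insertion and the way replicates were joined are not given in the sources used here. Per the labels, each group has 1 peak file for its 3 samples, so peaks belong to a group and not to a sample. The deposited files give a start and an end for each peak, and the score that the authors deposited with each peak is 1 in every row, so it carries no peak height. Nearly all peaks have 1 width per list, 219 bp for WT (38249 of 38258) and 193 bp for KO (36176 of 36182). The lists cover 8.38 Mb and 6.98 Mb. The peak names are numbered within each chromosome, and the row order follows these numbers (Spearman correlation per chromosome, across peaks, between 0.991 and 0.998). The highest numbers sum to 58679 and 51257, of which 65.2% and 70.6% are present, so peaks had been removed from both lists.

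Everything after the peak lists was computed here with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9. A peak was shared when a peak of the other list overlapped it by at least 1 bp. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Chance overlap came from 100 random placements of the KO peaks. With no values per replicate no test across replicates was made and no p-value is given. The overlap code was compared with bedtools 2.31.1 on 800 simulated peaks and gave 0 differences.

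Genes were taken from a RefSeq table of assembly GRCm38.p6, which has the coordinates of mm10. It gives the start and end of each gene but no strand, transcription start or exons as used here, and no genome sequence was used. The design fixed before the data were examined asked for distances to transcription start sites, for exons and introns, and for 21 sequence motifs. In their place peaks were sorted into those within 1 kb of either end of a protein-coding gene, those in a gene body and those between genes, and the motif content was left out. Gene-end peaks of a gene were counted in each list by midpoint, without a check of overlap. A gene with a gene-end peak in one list alone can therefore hold a shared peak near the limit. The design had also planned to assign each peak to the gene with the nearest transcription start within 100 kb, which was not done. The closest setting to that plan, the gene with the nearest end, is given as an alternative. In the main analysis a peak was instead assigned to the protein-coding gene that holds its midpoint, and otherwise to the nearest one within 100 kb. The list counts and the ranking of named genes used this assignment. By this rule 94.3% of WT and 95.0% of KO peaks lay within reach of a gene, and 14417 of 21887 genes received a peak. Nearest-gene assignment does not show which gene a site acts on.

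The 22 gene lists, of 346 distinct genes that were all found in the table, were fixed before the data were examined. For each list, KO-only minus WT-only peaks over its members was given as a percentile among 10000 random lists matched on peaks per gene in 10 bins. A list at or below 2.5 or at or above 97.5 was called. These percentiles describe the 2 lists of peaks and are not p-values. The top bin, with 25 or more peaks per gene, holds 29 genes, among them Bach2 and Foxp1, which limits the match for lists with these genes. The step was tested on simulated data for 21887 genes, 200 of them with 4 times the odds of KO-only peaks. Of 100 lists of 20 changed genes, 100% reached the upper bound, and 6% of 100 lists of unchanged genes lay outside the bounds. Both kinds of list held only genes with at least 2 genotype-specific peaks, and each peak was drawn independently of others at its gene. The fixed lists also hold genes with fewer peaks, so these rates may not carry over to them.

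The genes named follow a rule fixed before the data were examined: Bcl11b, Foxp3, Il2ra, Ctla4, Ikzf2 and Il10 always, the 10 genes at each end of the ranking by KO-only minus WT-only peaks, and in each list up to 3 members per direction with a difference of at least 2 peaks. A part of the rule that needed a peak score could not be applied. A gene that the rule names is not reported here. S1pr1, Tcf7, Prf1, Klrk1, Fcer1g, Nkg7, Cd244a, Il2rb, Gzmk, Firre, 4933407K13Rik and Xist lie outside the rule and were chosen after their values were seen. The same holds for Tyrobp, Ccl3, Ccl4 and Cd8a. Ifng and Fcgr3 also lie outside the rule and are named only as members left out of a list. Alternatives were another overlap rule, the first part of each list by row order, autosomes alone, another gene-end window, other assignments of peaks to genes, other matching of random lists, and lists without their 2 members with most genotype-specific peaks.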

Results

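Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in regulatory T cells (Treg cells) sorted as CD4-positive, YFP-positive cells from mouse spleen and draining lymph nodes. The YFP and Cre recombinase were expressed from the Foxp3 gene, which encodes the lineage-defining transcription factor of Treg cells. The 6 samples fell into 2 groups of 3, one with intact Bcl11b (WT) and one labelled Bcl11b knockout (KO), with 100000 cells lysed per sample. Each group was represented by 1 list of peaks for its 3 samples together, 38258 peaks for WT and 36182 for KO, on mouse build mm10. The lists carried no read counts, so the depth per sample is unknown, no spread between replicates could be measured, and no difference below has a replicate check. A peak in one list that no peak of the other list overlapped is called WT-only or KO-only. Such a peak was not called in the other list, which does not show that the site was closed there.

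The first question was what the lists hold at the targeted gene and at genes that define Treg cells. Bcl11b, which encodes a zinc-finger transcription factor of T cells and spans chromosome 12 from 107910403 to 108004145, had 5 WT-only, 5 KO-only and 6 shared peaks, and the peak at its upper gene end (WT list, 108003932 to 108004150) was shared. Of the WT-only peaks of Bcl11b, those at 107928126 to 107928344 and 107940819 to 107941037 lay in the gene body. The labels do not give the deleted part of the gene, so these peaks do not check the knockout. At Foxp3 on chromosome X, 1 peak inside the gene (WT list, 7584020 to 7584238) was shared and no genotype-specific peak was assigned to the gene. Within 20 kb of Foxp3, a window chosen after seeing the data that also counts peaks assigned to neighbouring genes, lay 4 shared, 1 WT-only and 1 KO-only peaks. Ctla4, an inhibitory receptor of Treg cells, had 11 shared, 2 WT-only and 2 KO-only peaks, and its WT-only peaks stood at 60902613 to 60902831 and 60916457 to 60916675 on chromosome 1. Both lay within 20 kb of Ctla4, where 0 KO-only peaks were found. Il2ra, the IL-2 receptor alpha chain, had 2 WT-only, 2 KO-only and 4 shared peaks. Il10, an inhibitory cytokine, had 1 WT-only, 1 KO-only and 5 shared peaks, and its KO-only peak (chromosome 1, 131025882 to 131026074) had its midpoint 1.01 kb beyond the gene. Ikzf2, which encodes the Treg factor Helios, had 4 WT-only, 7 KO-only and 10 shared peaks (KO-only share 63.6%, exact 95% interval 30.8 to 89.1%), and within 20 kb of Ikzf2 the numbers were 1, 6 and 8.

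**Figure D1:**
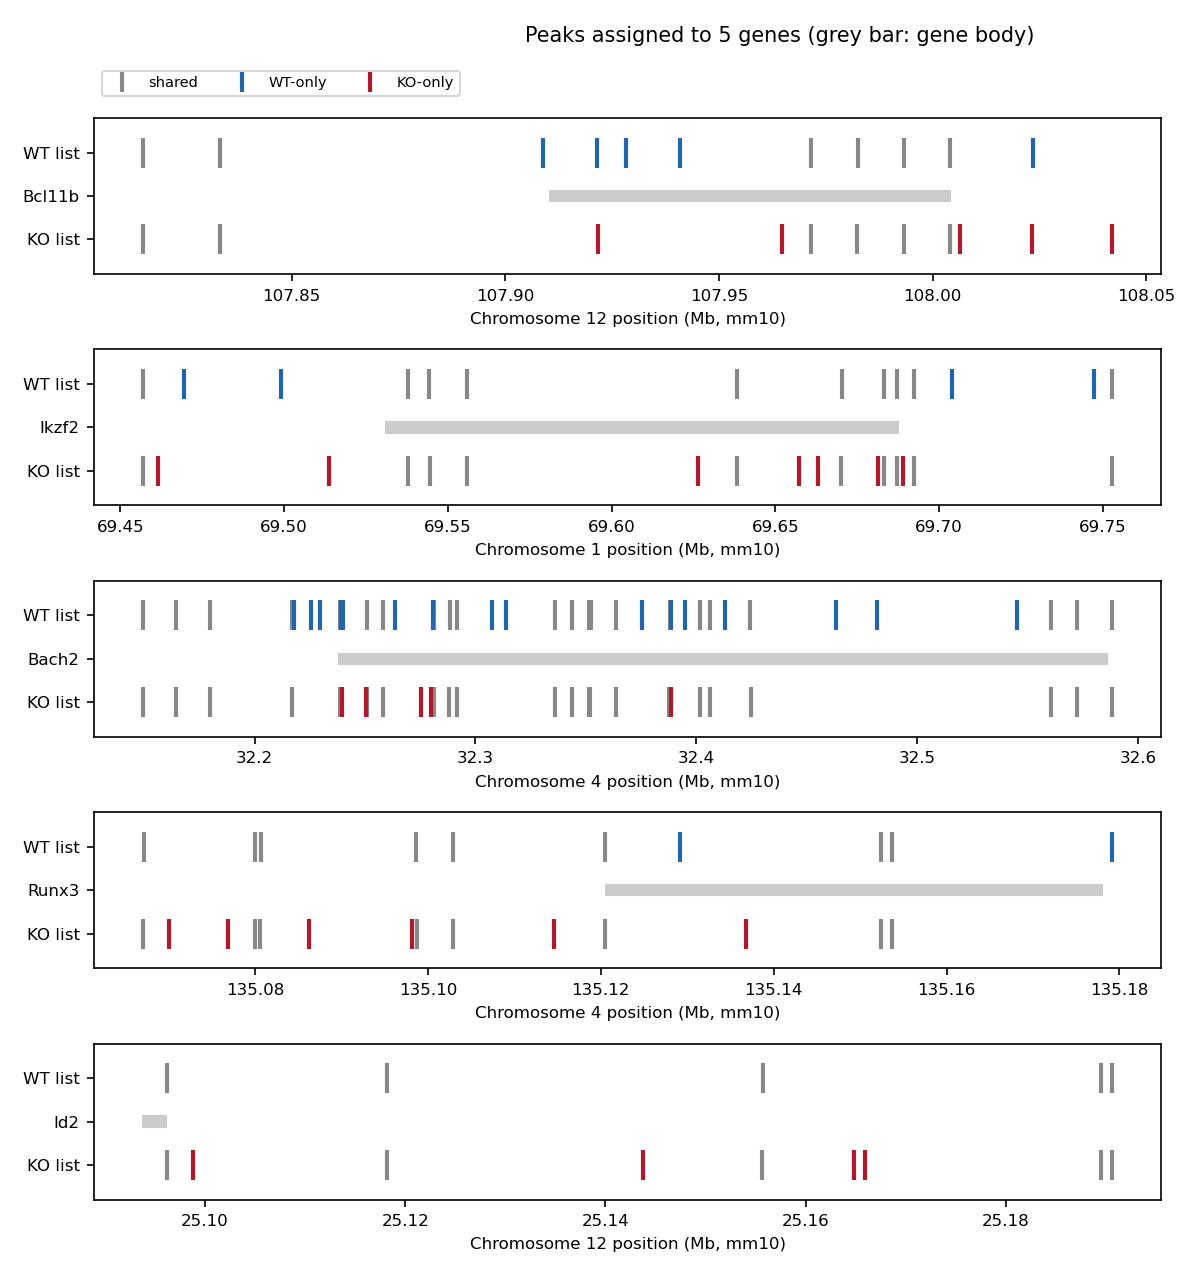
Positions of the peaks assigned to Bcl11b, Ikzf2, Bach2, Runx3 and Id2 (horizontal axis, chromosome position in Mb, mm10), with the WT list above and the KO list below the gene body in grey; grey ticks are shared, blue WT-only and red KO-only peaks. Bach2 had 16 WT-only and 5 KO-only peaks, and Id2 had 0 WT-only and 4 KO-only peaks.

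The next comparison asked at which genes the lists differed most. Among all protein-coding genes, the largest surplus of WT-only peaks under the main assignment was at Hdac9, a class IIa histone deacetylase gene on chromosome 12, with 15 WT-only, 0 KO-only and 3 shared peaks, the WT-only ones all in the gene body. With peaks given to the gene with the nearest end, KO-only minus WT-only peaks numbered -4 at Hdac9, smaller in size than the -12 at Pls3 and the -10 at Arid5b. Bach2, a repressor that restrains effector differentiation of T cells, had 16 WT-only and 5 KO-only peaks among 22 shared ones, and Foxp1, a factor of resting T cells, had 17 and 8 among 23 shared ones. Arid5b (10 against 0), Frmd4b (10 against 1), Ubash3b (10 against 2), Cdk19 (11 against 3), Ntn4 (8 against 0) and Thada (8 against 0) completed the autosomal genes of this end. By the nearest end, the difference was -6 at Bach2, -3 at Foxp1, -5 at Frmd4b, -4 at Cdk19 and -2 at Thada. The first 50% of each list holds fewer genotype-specific peaks in all, and the differences at this end were smaller there. They were -4 at Arid5b, -3 at Bach2 and -2 at Hdac9, Foxp1, Thada and Pls3. At Frmd4b, Cdk19, Ubash3b and Ntn4 they were -1. Pls3 on the X chromosome, with 13 against 1, owed its place to peaks in a neighbouring noncoding locus described with the chromosomes. At the other end, Fmnl2, a formin gene, had 13 KO-only, 5 WT-only and 0 shared peaks. Pde4b, a cAMP phosphodiesterase gene, and Septin9 each had 9 KO-only against 3 WT-only peaks. In the first 50% of each list the surplus was 2 at both genes, and within 10 kb it was 2 at Pde4b and 6 at Septin9. Zfp407 had 8 against 2, and Myo16 and Trerf1 each had 7 against 1. By the nearest end the surplus was 1 peak at Zfp407 and at Myo16, and at Trerf1 it was 0 in the first 50% of each list. Also at this end were 4930467E23Rik (9 against 1), Gm40469 (7 against 1) and Zfp984 (7 against 0), which belong to families of near-identical copies, so their peak calls are uncertain. At Gm40469 and Zfp984 the difference was also 0 in the first 50% of each list. A surplus of 5 or more WT-only peaks was found at 81 genes and one of 5 or more KO-only peaks at 25 genes. Assigned WT-only peaks numbered 10254 and KO-only peaks 8515, so these counts do not start from an even baseline.

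At genes of naive and resting T cells, WT-only peaks outnumbered KO-only peaks, while most peaks were shared. The 18 members had 73 WT-only, 37 KO-only and 137 shared peaks, a KO-only share of 33.6% (exact 95% interval 24.9 to 43.3%) against 45.4% over all assigned genotype-specific peaks. WT-only peaks were more numerous at 11 members and KO-only peaks at 0. Bcl2, a survival gene, had 8 WT-only and 2 KO-only peaks, a direction that turned in the first 50% of each list by row order. S1pr1, the receptor for egress from lymphoid organs, had 4 and 2, and Tcf7, a factor of naive and stem-like T cells, had 1 and 0. By midpoint, a gene-end peak of Tcf7 was counted in the WT list alone, which does not show that this peak was WT-only. The list stood at percentile 1.38 of 10000 random lists matched on the number of peaks per gene. Its place outside the bounds rested on Bach2 and Foxp1, the members with most genotype-specific peaks. They also had the largest surplus of WT-only peaks in the list, so their removal lowers the difference by construction. Without those members 40 WT-only and 24 KO-only peaks remained. The percentile was then 17.2, inside the bounds that 95% of random lists keep to. It was also inside them, at 2.66, when a peak had to lie within 10 kb of its gene, and at 3.65 when peaks went to the gene with the nearest end.

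At genes of cytotoxic, NK and innate lymphoid cells, KO-only peaks outnumbered WT-only peaks, with shared peaks the most numerous class. The 24 members had 31 KO-only, 12 WT-only and 47 shared peaks, a KO-only share of 72.1% (56.3 to 84.7%), with more KO-only peaks at 13 members and more WT-only peaks at 2. Id2, a transcriptional regulator required for innate lymphoid and NK cells, had 4 KO-only and 0 WT-only peaks, the nearest at 25098754 to 25098946 on chromosome 12. Eomes, a T-box factor of NK and CD8 T cells, had 3 and 1, the death ligand gene Fasl 4 and 2, and the perforin gene Prf1 3 and 1. The differences at Eomes and Fasl were 0 within 10 kb of the gene and in the first 50% of each list. At Id2 the difference was 1 within 10 kb and 3 in the first 50% of each list. Klrk1, encoding the activating receptor NKG2D, and Fcer1g, a signalling adaptor, each had 2 KO-only and 0 WT-only peaks. Counted by midpoint, a gene-end peak was in the KO list alone at Nkg7, Klrk1, Fcer1g, Cd244a and Il2rb. It was in the WT list alone at the granzyme gene Gzmk. This count does not check overlap, so such a peak may be shared. The list stood at percentile 99.995, with 1 of the 10000 random lists reaching its difference.

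KO-only peaks also outnumbered WT-only peaks at Th1 genes, with 30 against 19 over 16 members (percentile 98.79), at 9 members against 4. Runx3, a factor of Th1 and CD8 T cells, had 6 KO-only and 2 WT-only peaks, and Tbx21, encoding T-bet, had 4 KO-only peaks between 97101913 and 97114944 on chromosome 11 against 1 WT-only peak. The difference was 0 within 10 kb for Runx3 and in the first 50% of each list for Tbx21. Ifngr1, a chain of the interferon gamma receptor, had 1 and 3, which also turned there. Myeloid genes had 12 KO-only and 5 WT-only peaks over 18 members (percentile 98.3), among them 3 and 0 at Itgam, an integrin of myeloid and NK cells. Both lists lay inside the bounds under several other settings, with the Th1 list at percentile 78.0 when peaks counted for every gene within 10 kb and the myeloid list at 75.1 in the first 50% of each list by row order. Across 22 lists, 4 lay outside the bounds, where 1.1 would if each were a random list of genes. The lists share members, and random lists do not measure variation between replicates, so this count is not a test of genotype.

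The Treg signature list had 56 KO-only and 52 WT-only peaks over 30 members (percentile 93.4), with 8 members in each direction. Dusp4, a phosphatase of MAP kinases, had 5 KO-only and 1 WT-only peaks, Nrp1, a receptor of thymus-derived Treg cells, had 4 and 1, and Nt5e, the ectonucleotidase CD73, had 0 and 3. Effector Treg and homing genes had 30 KO-only and 31 WT-only peaks (percentile 74.7), with 2 and 0 at the receptor gene Klrg1 and 0 and 4 at the adhesion receptor gene Cd44. For genes of IL-2 and STAT5 signalling the numbers were 34 and 26 (percentile 96.3), with 5 and 0 at the kinase gene Pim1. The direction turned to 20 and 22 within 10 kb and to 21 and 24 over gene bodies with 10 kb, and the percentile was 97.8 with the 500 bp gap and 99.4 without Bcl2 and Jak1. Metabolism and mTOR genes had 23 and 15 (percentile 96.3), with 4 and 0 at Rptor, the Raptor subunit of mTORC1, and at Pfkfb3, a regulator of glycolysis, and 0 and 5 at Hif1a. That list lay outside the bounds within 10 kb (percentile 99.1), over gene bodies with 10 kb (99.5) and without Hif1a and Slc2a3 (98.8). T cell receptor activation genes had 35 and 31 (percentile 91.2), with 5 and 0 at Nfatc2 and 0 and 3 at Rel. T cell identity genes had 48 and 64 (percentile 37.1), with 0 and 6 at Themis, a regulator of T cell selection, and 4 and 1 at the adaptor gene Skap1. In the first 50% of each list the difference was 0 at Nt5e, Rptor, Hif1a, Nfatc2 and Themis.

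Helper programmes other than Th1 lay inside the bounds under the main settings. Th2 genes had 19 KO-only and 13 WT-only peaks (percentile 94.1, and 97.6 with the 500 bp gap, outside the bounds), and Th17 genes 12 and 19 (percentile 20.7). Csf2, encoding GM-CSF and a member of both lists, had 3 KO-only peaks and no other, none of them in the first 50% of the list, whereas Ahr, the aryl hydrocarbon receptor, had 1 and 5. Follicular helper genes had 21 and 30 (percentile 35.9), co-inhibitory receptor genes 22 and 26 (percentile 62.0), and transcription factors of Treg chromatin 75 and 85 (percentile 70.6), with 4 and 0 at Ikzf1, encoding Ikaros. Without Foxp1 and Bach2 the last list turned to 62 and 52 and lay outside the bounds at percentile 98.1, and it also turned, to 28 and 24, in the first 50% of each list. Apoptosis genes had 25 and 23 (percentile 87.4) and cell cycle genes 14 and 12 (percentile 82.3). Among lists for other cell types and controls, CD8 T cell genes had 11 and 12 (percentile 61.1), B cell genes 9 and 7 (percentile 80.2), erythroid and megakaryocyte genes 1 and 5 (percentile 3.40), housekeeping genes 4 and 10 (percentile 20.5) and non-lymphoid genes 6 and 4 (percentile 85.5). Of these, the erythroid list lay outside the bounds with the 500 bp gap (2.23), over gene bodies with 10 kb (0.910) and with density-matched lists (2.095). The B cell list did so over gene bodies with 10 kb (98.2), and the non-lymphoid list, on the other side, in the first 50% of each list (2.29).

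**Figure D2:**
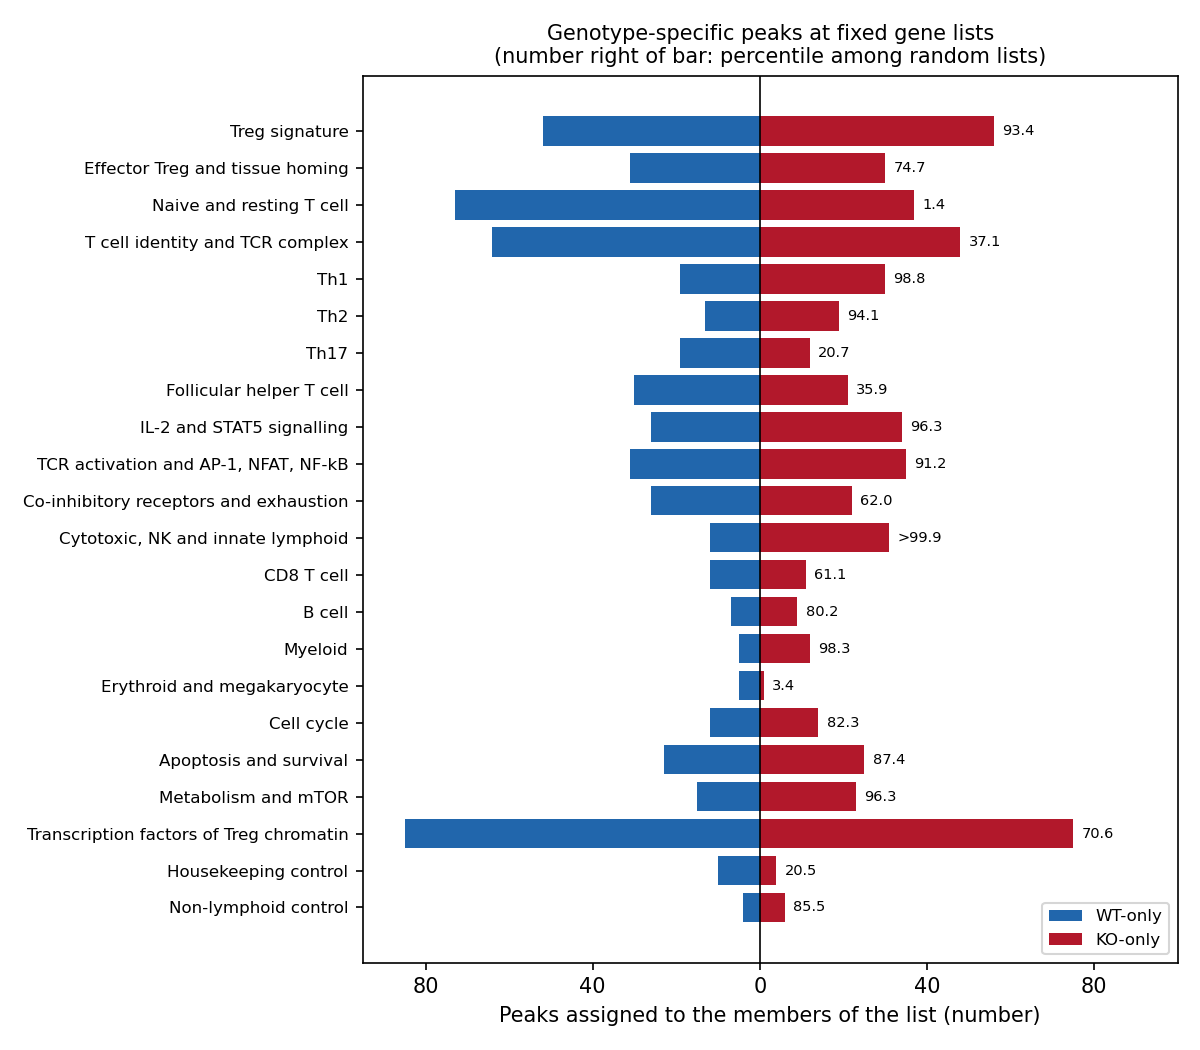
Numbers of WT-only peaks (blue, left of 0) and KO-only peaks (red, right of 0) assigned to the members of each of the 22 gene lists, with the percentile of KO-only minus WT-only peaks among 10000 random lists written beside each bar. The naive and resting T cell list had 73 WT-only and 37 KO-only peaks, and the cytotoxic, NK and innate lymphoid list had 12 and 31.

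Over the whole genome most peaks were called in both lists. Of the WT peaks, 26975 (70.5%, exact 95% interval 70.0 to 71.0%) overlapped a KO peak and 11283 were WT-only. Of the KO peaks, 26976 (74.6%, 74.1 to 75.0%) overlapped a WT peak and 9206 were KO-only. Since the numbers of shared peaks were near equal, the surplus of WT-only peaks reflects the longer WT list. With the WT list shortened to the KO length by row order, the counts were therefore near equal by construction (9765 against 9764). The direction turned in the first 50% of each list against the whole other list (1990 against 2367), where the shared shares were 89.6% for WT and 86.9% for KO. Randomly placed KO peaks overlapped a median of 0.593% of WT peaks over 100 placements. Counted by midpoint and without regard to overlap, protein-coding genes with a gene-end peak in both lists numbered 9073. Those with one in the WT list alone numbered 642 and in the KO list alone 599. The shared percentage depended on the place in the list: it was 96.6% in the first 10% of the WT list and 29.2% in its last 10%, and 95.9% and 44.9% in the KO list. The order of the lists, taken here as a rank of peak strength, is inferred and not stated by the labels. The intervals cover counting error only, and neighbouring peaks are not independent.

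**Figure D3:**
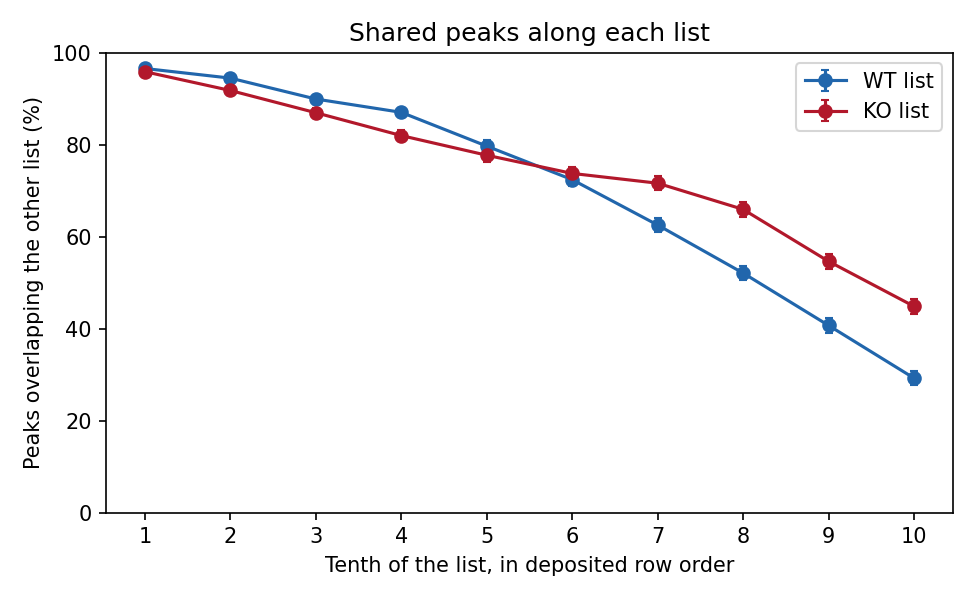
Percentage of peaks overlapping a peak of the other list (vertical axis) in each 10% of the WT list (blue) and the KO list (red), in row order (horizontal axis); bars are exact 95% intervals. The percentage was 96.6% in the first 10% and 29.2% in the last 10% of the WT list, and 95.9% and 44.9% in the KO list.

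Genotype-specific peaks lay away from gene ends more often than shared peaks. Within 1 kb of either end of a protein-coding gene lay 34.8% of shared peaks (34.3 to 35.4%), 13.1% of WT-only peaks (12.5 to 13.8%) and 16.9% of KO-only peaks (16.2 to 17.7%). Gene bodies held 34.9%, 46.7% and 43.8% of them, and the space between genes 30.3%, 40.2% and 39.3%. Regions rich in genes had a higher share of KO-only peaks: it was 39.4% (37.3 to 41.6%) of genotype-specific peaks where 0 to 2 genes lay within the surrounding 1 Mb and 51.4% (48.9 to 53.9%) where 32 to 72 did. WT-only peaks inside genes lay in longer genes, with a median length of 87.2 kb against 73.5 kb for KO-only and 50.4 kb for shared peaks. In the first 50% of each list the gene-end shares of WT-only and KO-only peaks were 32.7% and 32.0%, so the order between them seen in the whole lists did not hold there. Shared peaks stood at 47.4% there. The gene-end share of all peaks fell along the WT list, from 74.7% in the first 10% to 7.42% in the last 10%. In the KO list it fell from 70.9% to 9.26%. Genotype-specific peaks lay mostly late in the lists, so their location was not fully separated from their place in the list.

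The X chromosome differed from the autosomes in its share of KO-only peaks. It had 982 WT and 747 KO peaks, and 161 of its 557 genotype-specific peaks were KO-only (28.9%, 25.2 to 32.9%), against 45.4% (44.7 to 46.1%) on the autosomes. At gene ends the X chromosome had 318 WT and 316 KO peaks, and away from gene ends 664 and 431. The autosomes had 10550 and 10617 at gene ends, and 26699 and 24790 away from them. Inside the lncRNA gene Firre (chromosome X, 50563120 to 50635321) lay 13 WT-only, 1 KO-only and 1 shared peaks. Inside 4933407K13Rik (75725458 to 75764699), which covers the Dxz4 repeat next to Pls3, lay 13 WT-only and 1 KO-only peaks, and inside Xist, the lncRNA that coats the inactive X chromosome, 1 WT-only peak. These loci were chosen after the peaks of Pls3 had been seen. Without them 159 KO-only and 369 WT-only peaks remained on the X chromosome, a KO-only share of 30.1% (26.2 to 34.2%). The Y chromosome had 27 WT and 28 KO peaks. Among autosomes the share ran from 38.5% on chromosome 10 to 54.1% on chromosome 19. In the first 50% of each list the X share was 45.8% (34.8 to 57.1%, 83 peaks) and the autosomal share 54.5%.

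**Figure D4:**
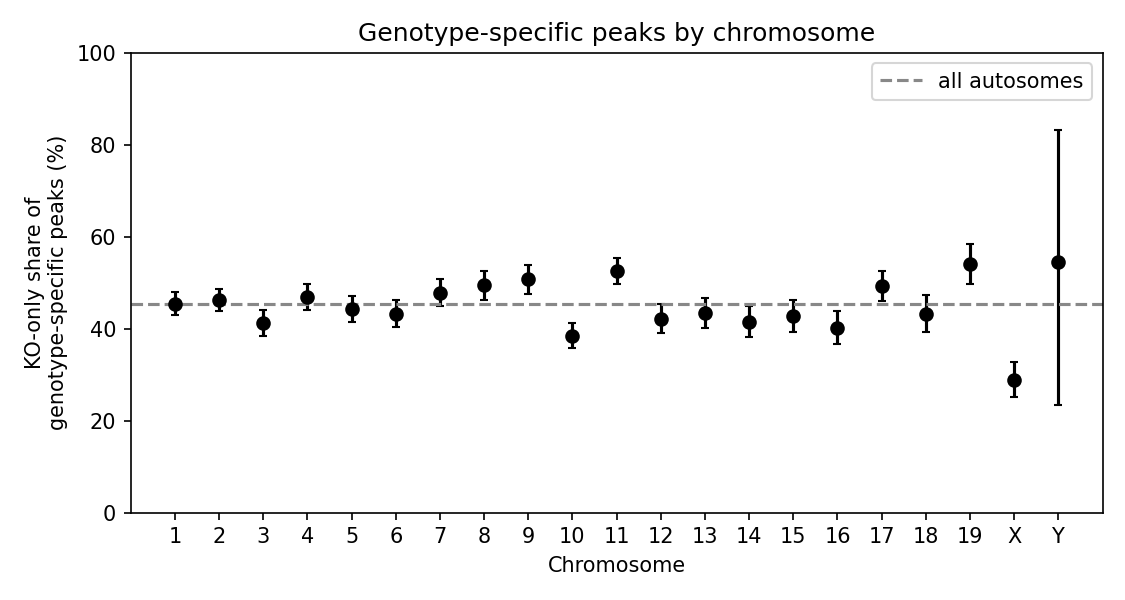
KO-only share of genotype-specific peaks in percent (vertical axis) for each chromosome (horizontal axis); points are shares, bars exact 95% intervals, and the dashed line is the share over all autosomes, 45.4%. The X chromosome is at 28.9%, and the Y chromosome, with 5 WT-only and 6 KO-only peaks, has a wide interval.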

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

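The settings that use row order, the nearest gene end, gene density or fewer members were chosen after seeing the data. The planned stricter selections by score or width gave no value, since the score is constant and the width nearly so, and the motif alternatives and leaving out replicates were not run. No paired analysis was possible because each list joins the 3 samples of its group. Depth is unknown, so how far it limits the calls cannot be given.

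The percentages of WT and KO peaks that were shared were 60.7% and 64.2% with 50% reciprocal overlap, 76.4% and 81.7% when a gap of up to 500 bp counted as overlap, and 73.0% and 73.0% with the WT list shortened to the KO length. Taking the first 50% of each list by row order against the whole other list gave 89.6% and 86.9%, with 1990 WT-only and 2367 KO-only peaks, so KO-only peaks were then the more numerous. Taking that part of both lists gave 75.1% and 79.4%, with 4762 and 3723 peaks. Looser or tighter matching shifts the first of these by construction. Equal list lengths also make the 73.0% and 73.0% near equal by construction. With the first part of both lists, the larger WT-only number follows from the longer WT part (19129 against 18091 peaks). For the first part against the whole other list the cause was not tested. The gene-end shares of WT-only and KO-only peaks were 8.14% and 9.76% with the 500 bp gap, 19.5% and 24.3% within 2.5 kb, and 32.7% and 32.0% in the first part of each list; for shared peaks they were 41.0% within 2.5 kb and 47.4% in the first part. The KO-only share of X-linked and autosomal genotype-specific peaks was 20.6% and 42.9% with the gap, and 45.8% and 54.5% in the first part.

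The cytotoxic, NK and innate lymphoid list stayed outside the bounds in all 7 settings, from 99.41 to 100. The naive and resting list moved to 2.66 (within 10 kb), 3.65 (nearest end) and 17.2 (without Foxp1 and Bach2). The Th1 list moved to 92.8 (within 10 kb), 78.0 (gene body and 10 kb), 96.2 (first part) and 97.3 (without Ifng and Runx3), and the myeloid list to 94.4 (within 10 kb), 75.1 (first part), 96.3 (density matched) and 89.1 (without Fcgr3 and Itgam). Apart from the removal of members, the cause was not tested. Of the 18 other lists, 7 lay outside the bounds in at least 1 setting, 12 values in all. The difference changed sign in at least 1 setting in 7 of the 22 lists, none of them called. Of 77 named genes with a difference, 8 changed its sign in at least 1 of 5 settings: Swap70, Bcl2, Cd6, Ifngr1, Rora, Cxcr5, Socs2 and Xcl1. A further 28 moved to 0 without changing sign in at least 1 setting, and 41 kept their sign in all 5.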

Other observations

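All tests of explanations in this part were chosen after the data had been seen; those of the end of the lists and of male cells for the X chromosome, and of NK or CD8 T cells, were also chosen after the result they measure had been seen.

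On the X chromosome, 28.9% of genotype-specific peaks were KO-only against 45.4% on autosomes. The location and gene density of the peaks are argued against as the whole cause, since autosomal peaks matched on both gave an expected 45.0%, above the interval of 25.2 to 32.9%. Weak calls near the end of each list stay open: in the first 50% of each list by row order the X share was 45.8% (34.8 to 57.1%, 83 peaks), an interval that holds the autosomal 54.5%. A different mix of male and female animals behind the lists may also have contributed, because Firre and Dxz4, with 13 WT-only and 1 KO-only peaks each, are known as sites open on the inactive X chromosome of female cells. That cannot be told apart from other causes: shared Y-linked peaks stood a median of 5.63% of the list higher in the KO list than matched autosomal ones, but the bootstrap 95% interval ran from -0.459 to 12.9 over 22 peaks, the loci were picked after the Dxz4 peaks were seen, and the sex of the animals is not given in the labels. Shared X-linked peaks from the first part of the WT list stood a median of -2.49% of the list from autosomal ones (-3.44 to -1.47, 387 peaks). A negative value is a lower place in the KO list. At X-linked gene ends the value was -2.15% (-3.71 to -1.01, 264 shared peaks). Positions were percentages of each list, set against autosomal peaks of similar WT position and location. The value of -2.49% was looked at after the test of the end of the lists. The first part leaves out the end of the WT list, but row order is an inferred rank of peak strength and shows no change in accessibility.

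The naive and resting T cell list, with 73 WT-only and 37 KO-only peaks, kept its place with random lists matched on gene density (percentile 0.845). That argues against gene density as the whole cause. It also kept its place in the first part of each list (percentile 1.47). This argues against weak calls as the whole cause only if row order ranks peak strength, which is inferred. A few genes with many peaks remain a candidate explanation, since the list stood at 17.2 without Foxp1 and Bach2, although all 11 members with a difference had more WT-only peaks. A loss of accessible sites at these genes with Bcl11b, the biological difference the design names, stays open and was not tested.

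The surplus of KO-only peaks at cytotoxic, NK and innate lymphoid genes is not accounted for by gene density (percentile 99.985 with density-matched lists). Without Fasl and Cd244a, the members with most genotype-specific peaks, the percentile was 99.98. That removal changed the difference only from 19 to 16 and kept Id2, the member with the largest difference, so it says little about a few genes. KO-only peaks were more numerous at 13 members and WT-only peaks at 2. NK or CD8 T cells among the sorted CD4-positive, YFP-positive cells stay open: 9 NK receptor and CD8 genes had 6 KO-only and 6 WT-only peaks, a KO-only share of 50% (21.1 to 78.9%), too few to decide. Most of these genes belong to the list itself, Cd8a had no assigned peak, and the NK receptor gene Klrk1, with 2 KO-only and 0 WT-only peaks, was not among them, so the even split depends on the choice of genes. Myeloid cells also stay open and were not tested separately: myeloid genes had 12 KO-only and 5 WT-only peaks (percentile 98.3), and Fcer1g, Tyrobp, Ccl3 and Ccl4 of the cytotoxic list are used by myeloid cells too. A change of chromatin in KO Treg cells may be involved as well, and these lists hold no test that separates it from a change in the cells that were sorted.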
